A study of Homo sapiens with 18 samples.

How the data were processed

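RNA-seq was made from total RNA of D425 cells in culture and of D425 tumours grown in the cerebellum of NOD-SCID mice, where oligonucleotide dosing began 14 days after injection and was repeated every 3 days. The authors deposited a table of raw counts of reads per gene for all 18 samples, and a table of TPM values for the cultures, per the labels. The submitters' processing notes name bcl2fastq 2.20, STAR 2.4.2a, featureCounts 2.0.1, DESeq2 1.34.0 and the genome build GRCh38.p13, without giving the role or order of each. The gene annotation, the strand setting and the treatment of reads that overlap several genes are not given in the sources used here, so that reads of overlapping or antisense genes may not be separated. The count table holds 90517 features, of which 31037 carry LNCipedia-style names and 40190 were matched by symbol to the GENCODE annotation of GRCh38 that supplied coordinates, biotype, GC content and length. The deposited TPM values have the same sum in each culture, and served only as an alternative.

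Samples were grouped by their titles. The names of 9 count columns of tumours did not show which schedule of the lnc-HLX-2-7 oligonucleotide they held, and these 9 columns were not used. The 6 planned comparisons among tumours, the overlaps and interaction between tumours and cultures, and a fit of all 18 samples were therefore not made. Of the tumours, 3 columns were taken as ASO-CTRL from their letter, without replicate numbers. They serve only in the closing observations and where the number of features with a count is given. The TPM table of the tumours was not used.

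The cultures were compared with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr by group, glmQLFit and glmQLFTest, two-sided, group as the only term), with genes called at a Benjamini-Hochberg adjusted p under 0.05. Library totals ran from 10793172 to 22956322 counts, so that a gene at 1 CPM had about 10 or more counts in each culture. Normalised CPM are counts over the TMM-scaled library total, in the usual CPM unit, given as mean ± SD over 3 libraries. Gene lists with at least 5 tested members were tested with camera and fry from limma 3.58.1, given the edgeR count data rather than log2 CPM. Camera was run with a preset correlation of 0.01 and again with an estimated one. Fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, gave adjusted p from 7.84e-06 to 0.0622 over these lists. A fold against a group at 0 counts is a bound from a floor of 3 counts over the group, which covers counting error only. Pairs of replicates of a group differed by more than counting noise (chi-square per gene 1.29 to 1.76), a spread that library preparation alone can give and that does not show separate cultures.

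The genes named follow a rule fixed before the data were examined, as were the 30 gene lists. It takes HLX, HLX-AS1, MYC, TBX2 and LIN9, the annotated genes within 200 kb of HLX, and the 10 highest and 10 lowest log2 fold changes among called genes with a symbol, a mean of at least 5 CPM and no overlap between groups. It adds, for each list called by camera or with at least 3 called members, up to 4 called members with the smallest p. Some genes that the rule names are not reported here. Genes named outside this rule are said to have been named after their values were seen. The lists held MYC targets, cytosolic ribosomal proteins, histones, S phase, G2 and mitosis, oxidative phosphorylation, mitochondrially encoded genes, the tricarboxylic acid cycle, glycolysis, hypoxia, p53 targets, interferon response, amino acid and unfolded protein stress, cholesterol synthesis, immediate early and heat shock genes, medulloblastoma subgroup markers, photoreceptor genes, neuronal, stem and mesenchymal genes, long noncoding RNAs and markers of other brain cell types.

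The test was checked on simulated counts of 20513 genes with the means and library sizes of this comparison and 200 changed genes. It recovered 58.2% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 92.4% of those changed 4-fold, and 2.5% of its calls were false. The simulated changes were few, as many up as down, with a single spread for all genes. In the data 71.1% of genes were called, so this check does not cover the scaling under so broad a change. GC content and transcript length were fitted out of each library as splines with 5 degrees of freedom over 13055 protein-coding genes, of the longest transcript of each gene. On simulated data with a GC trend this lowered false calls from 7715 to 11 and kept 92.5% of the 200 changed genes. Those changes were few, balanced and placed without regard to GC content, whereas 80.4% of protein-coding genes were called in the data. The check does not show whether the correction also removes real changes that follow GC content or length.

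Alternatives fixed beforehand were DESeq2's median-of-ratios factors, no low-count filter, at least 10 counts in every library of a group, DESeq2 1.42.0, the replicate number as a block, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean of at least 1 TPM, leaving out mitochondrial, ribosomal protein and haemoglobin genes, and leaving out each replicate. Added after the data were seen were total counts without TMM factors, glmTreat against a 2-fold change, all libraries thinned to the smallest total, the GC and length correction, and a fit of 9 libraries. A scan over 30 neighbouring protein-coding genes with a mean of at least 5 CPM, and 1000 random gene orders, was also added after the data were seen. Figures were drawn with matplotlib 3.10.9.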

Results

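RNA was sequenced from D425, an established human medulloblastoma cell line of the Group 3 subgroup, grown in culture and as tumours in the cerebellum of NOD-SCID mice. The 18 samples fell into 6 groups of 3. Of the cultures, 3 carried a control short hairpin RNA (sh-CTRL) and 3 a hairpin named for HLX (sh-HLX), the homeobox transcription factor gene next to which the long noncoding RNA lnc-HLX-2-7 lies. The tumours received a control antisense oligonucleotide for 24 days (ASO-CTRL), or an oligonucleotide against lnc-HLX-2-7 for 24 days, for 36 days, or for 24 days followed by 12 days without it. Total counts were 21027735, 21927572 and 22956322 in the sh-CTRL cultures and 14564341, 10793172 and 13476784 in the sh-HLX cultures. The comparison given here is that of the sh-HLX with the sh-CTRL cultures, which asks what differs when HLX is targeted. The groups of tumours that received the lnc-HLX-2-7 oligonucleotide were not analysed here.

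HLX (ENSG00000136630, chromosome 1, 220879400 to 220885059, plus strand, GRCh38) was measured first, in every culture. Its counts were 200, 208 and 245 in the sh-CTRL libraries and 89, 66 and 85 in the sh-HLX libraries, or 10.9 ± 0.778 against 5.66 ± 0.0780 normalised CPM (mean ± SD, n = 3 each). The log2 fold change, sh-HLX minus sh-CTRL, was −0.95 (SE 0.111), with an adjusted p of 4.73e-12 by edgeR's quasi-likelihood test. MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434), the oncogene that drives growth in many Group 3 tumours, fell from 1109 ± 43.6 to 502 ± 5.66 CPM (SD, n = 3), a log2 fold change of −1.14 (SE 0.026, edgeR adjusted p = 2.92e-52). LIN9, which encodes a subunit of the MuvB complex that regulates cell cycle genes, fell from 49.1 ± 1.10 to 32.7 ± 1.04 CPM (log2 fold change −0.59, edgeR adjusted p = 1.67e-17). TBX2, a T-box transcription factor gene, was higher in the sh-HLX cultures, at 5.01 ± 0.568 against 3.21 ± 0.202 CPM (log2 fold change 0.63, SE 0.155, edgeR adjusted p = 2.42e-04). With GC content and transcript length fitted out of each library, the change of TBX2 was 0.29 and its adjusted p 0.0773, so that its call ended. Of the other annotated genes within 200 kb of HLX, C1orf115 (log2 fold change 0.80) and MTARC2 (0.44) rose, and MTARC1, LINC01352, RNU6ATAC35P and the antisense gene HLX-AS1 had too few counts to test. HLX-AS1 had 1, 0 and 1 counts in the sh-CTRL libraries and 0 in each sh-HLX library. Of the long noncoding RNAs listed under an HLX name and looked up after the values were seen, lnc-HLX-2 had 0 or 1 count per culture, and lnc-HLX-3 fell from 3.44 ± 0.512 to 0.895 ± 0.200 CPM (SD, n = 3; log2 fold change −1.93). The isoform lnc-HLX-2-7 was not matched to a feature, and no value is given for it.

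**Figure D1:**
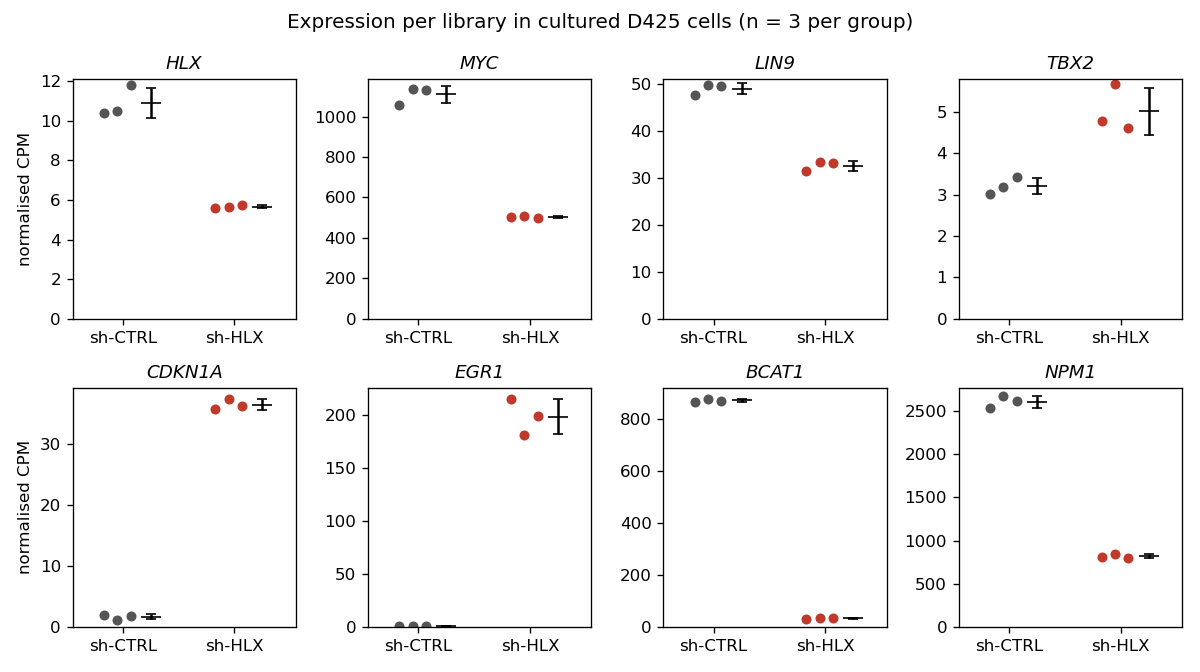
Normalised CPM (vertical axes, linear, from 0) of 8 genes in each cultured D425 library, with sh-CTRL in grey and sh-HLX in red; points are libraries, and the black mark with its bar is the group mean ± SD (n = 3). HLX, MYC, LIN9, BCAT1 and NPM1 lay lower in the sh-HLX libraries and TBX2, CDKN1A and EGR1 higher, with no overlap between the groups; EGR1 went from 1.49 to 198.7 CPM, and the call of TBX2 ended with GC content and length fitted out.

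EGR1 and FOS, immediate early genes that cells switch on within minutes of a stimulus, had the greatest increases among called genes with a mean of at least 5 CPM and no overlap between groups. EGR1 rose from 1.49 ± 0.157 to 198.7 ± 16.8 CPM (SD, n = 3; log2 fold change 7.06, SE 0.0767), FOS by 6.60 and JUN by 4.76 on the log2 scale. The cyclin-dependent kinase inhibitor gene CDKN1A, encoding p21, rose from 1.71 ± 0.398 to 36.5 ± 0.871 CPM (log2 fold change 4.41), and the carbonic anhydrase gene CA2 and the retinol dehydrogenase gene DHRS3 rose by 5.12 and 4.67. IQCN (5.61), RENBP (4.45), LARP6 (4.13) and the noncoding lnc-RHOB-1 (5.71) completed the 10 highest log2 fold changes. Among the lowest were genes of amino acid metabolism: BCAT1, a branched-chain aminotransferase, fell from 870.1 ± 6.05 to 34.1 ± 1.78 CPM (log2 fold change −4.67), the cystine transporter SLC7A11 from 149.9 ± 3.09 to 6.74 ± 0.873 (−4.46), and the argininosuccinate synthase ASS1 from 623 ± 15.6 to 29.4 ± 0.152 (−4.40). INHBE, an inhibin subunit gene, changed by −4.89, the glycosyltransferase gene GALNT13 by −4.79, MUC3A by −5.71, SGCD by −4.24, CHRND by −4.03 and NELL1 by −3.95. The lowest was lnc-LMTK2-2, with 192, 238 and 186 counts in sh-CTRL and 1, 0 and 2 in sh-HLX (log2 fold change −7.04). Each of these 20 genes had an edgeR adjusted p no higher than that of NELL1, 2.63e-30.

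The change was broad. Of 20513 genes tested with edgeR, 14576 (71.1%) were called at an adjusted p below 0.05, 7196 higher and 7380 lower in sh-HLX. Of these, 2573 were at least 2-fold higher and 2344 at least 2-fold lower. This split was 3806 to 1619 with total counts only, and 3111 to 932 with limma on log2(TPM + 1). Among protein-coding genes 10499 of 13056 were called, and among features with LNCipedia-style names 1982 of 3707. The groups did not overlap for 72.5% of genes, where chance gives 10% for 3 against 3. The replicates lay close together, with a biological coefficient of variation of 2.09%, and no label says that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The split of calls depended on scaling: with total counts only, log2 fold changes shifted by 0.26 at the median and 10070 genes were higher and 5055 lower, and with limma on log2(TPM + 1) the median shift was 0.29 and the split 9893 to 3928. Fold changes here are relative to the trimmed mean of M-values (TMM) factors. Ribosomal protein genes took 7.79% to 7.98% of counts in the sh-CTRL and 6.13% to 6.34% in the sh-HLX libraries, and the 10 most abundant genes 4.35% to 4.38% against 3.62% to 3.74%. Fewer features had a count in the sh-HLX libraries, 38677 to 41767, than in the deeper sh-CTRL libraries, 53099 to 55620. Depth need not be the whole reason. The ASO-CTRL tumours, with totals of 10266320 to 11818249, had 47144 to 48415 features with a count, but may also hold mouse reads. With no low-count filter, 4183 genes were called at least 2-fold higher and 7299 at least 2-fold lower.

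Growth genes fell together. Of 36 MYC targets of ribosome biogenesis and growth, 35 fell, 0 rose and 1, NOP2, was not called (0.37), with a median log2 fold change of −0.88; with total counts only, 32 fell and 3 rose. NPM1, the nucleolar protein nucleophosmin, fell from 2606 ± 69.6 to 823 ± 20.9 CPM (SD, n = 3; −1.66), the mitochondrial chaperonin HSPD1 changed by −1.22, PA2G4 by −1.15 and the nucleolar protein NCL by −1.06. Camera on the edgeR data, with a preset correlation of 0.01, gave this list an adjusted p of 1.20e-24, against an adjusted p of 0.134 with an estimated correlation. All 51 cytosolic ribosomal protein genes fell (median −0.61), among them RPS6 (−1.16), RPS24 (−0.98), RPL4 (−0.91) and RPL15 (−0.82). With total counts only, 44 fell and 4 rose. The camera adjusted p was 5.38e-27, and 0.252 with an estimated correlation. Of 26 replication-dependent histone genes 25 fell (median −0.996), among them H3C10 (−1.26), H2BC11 (−1.25), H3C12 (−1.25) and H2BC5 (−1.13). The exception was H3C8, named after its values were seen, at 0.186 against 1.59 CPM (3.07); the camera adjusted p was 2.25e-33, and 0.134 with an estimated correlation. These histone genes are near-identical in sequence, so that the counts of single members are uncertain.

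Cell cycle genes did not all move one way. Of 32 genes of S phase and DNA replication, 27 fell and 5 rose (median −0.32; camera adjusted p = 1.27e-05, and adjusted p = 0.240 with an estimated correlation). RFC3 (−1.50), POLA1 (−1.26) and the replicative helicase subunits MCM7 (−0.79) and MCM3 (−0.75) fell. Of 34 genes of G2 and mitosis, 26 fell, 4 rose and 4 were not called (median −0.39; camera adjusted p = 1.52e-05, and adjusted p = 0.318 with an estimated correlation). The kinesin CENPE (−1.46), BUB1B (−0.88), TOP2A (−0.83) and CDK1 (−0.76) fell, while the proliferation marker MKI67, named after its values were seen, rose by 0.36. With total counts only, 16 S phase genes fell and 8 rose, and 21 mitotic genes fell and 11 rose. With limma on log2(TPM + 1), 13 S phase genes fell and 11 rose (median −0.01), and 17 mitotic genes fell and 11 rose (median −0.0754). The change of CDK1 was −0.24 with GC content and length fitted out.

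Of 44 nuclear genes of oxidative phosphorylation, 41 fell, 2 rose and 1 was not called (median −0.42; camera adjusted p = 1.53e-08, and adjusted p = 0.325 with an estimated correlation). Those with the smallest edgeR p were the ATP synthase subunits ATP5F1B (−1.10), ATP5F1A (−1.09), ATP5MC1 (−0.83) and ATP5F1C (−0.76). By fold change they did not stand apart, since NDUFA9 (−1.097) fell more than ATP5F1A. With total counts only, 27 of these 44 fell and 8 rose, and with limma on log2(TPM + 1) 24 fell and 9 rose. The change of ATP5F1C was −0.34 with GC content and length fitted out. Of 19 genes of the tricarboxylic acid cycle, 13 fell, 3 rose and 3 were not called (median −0.37; camera adjusted p = 1.00e-03, and adjusted p = 0.318 with an estimated correlation), among them MDH1 (−0.93), FH (−0.81), MDH2 (−0.75) and PDHA1 (−0.69). With total counts only, 10 of these 19 fell and 6 rose, the median was −0.11 and the camera call ended (adjusted p = 0.0565), and with limma on log2(TPM + 1) 8 fell and 6 rose. Glycolysis genes went both ways, 12 of 22 down, 8 up and 2 not called (median −0.48; camera adjusted p = 4.95e-04, and adjusted p = 0.282 with an estimated correlation). PFKP (−1.82), LDHB (−1.22), PFKM (−1.18) and ENO1 (−0.95) fell. The largest changes, named after their values were seen, were those of PFKFB3 (3.34) and HK2 (−3.32). The glycolysis median was −0.22 with total counts only and −0.17 with limma on log2(TPM + 1), with 12 down and 8 up in each. Of the 13 mitochondrially encoded genes 11 fell, 1 rose and 1 was not called (median −0.37; camera adjusted p = 2.40e-03, and adjusted p = 0.467 with an estimated correlation). MT-ND6 (−2.37), MT-ATP8 (−1.57), MT-ND5 (−1.05) and MT-ND2 (−0.60) fell. With total counts only, 7 of the 13 fell and 4 rose and the camera call ended (adjusted p = 0.0725), and with limma on log2(TPM + 1) 4 fell and 3 rose. With GC content and length fitted out, 8 rose and 3 fell, and the list's median turned to 0.14. There MT-ND6 was at −1.52, MT-ND2 at −0.0993 and MT-ATP8 at −0.05 (adjusted p = 0.627), and some of these genes overlap neighbours whose reads the counting may not separate. The 1 that rose, MT-CO1, named after its values were seen, was the most abundant of the 13, at 4458 CPM in sh-CTRL and 5109 in sh-HLX (0.20). All mitochondrial features together took 1.21% to 1.27% of raw counts in sh-CTRL and 1.48% to 1.58% in sh-HLX. These shares use no TMM factors and include features beyond the 13 genes. Of 20 hypoxia response genes, 10 fell, 7 rose and 3 were not called (camera adjusted p = 0.0106, and adjusted p = 0.214 with an estimated correlation), with PDK1 (−1.80), CA12 (−1.48), VEGFA (−1.41) and NDRG1 (−1.23) lower. The largest change of that list, named after its values were seen, was the rise of ADM from 0.766 to 5.97 CPM (2.95). The hypoxia median of −0.20 turned to 0.07 with total counts only, 0.10 with TPM and 0.01 with GC content and length fitted out.

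Of 20 immediate early and heat shock genes 18 rose and 2 fell (median 1.35; camera adjusted p = 1.52e-19, and adjusted p = 0.0908 with an estimated correlation). The cochaperone DNAJB1 rose by 1.49, and, named after their values were seen, FOSB rose by 4.02 and DUSP1, a phosphatase that shuts off MAP kinases, by 2.14. The 2 that fell, also named afterwards, were HSPE1 (−1.08), the partner of HSPD1, and the constitutive chaperone HSPA8 (−0.36). Of 30 p53 targets and apoptosis genes 21 rose, 7 fell and 2 were not called (median 0.49; camera adjusted p = 5.18e-06, and adjusted p = 0.134 with an estimated correlation). With total counts only, 23 rose and 2 fell (median 0.76), and with GC content and length fitted out 20 rose and 7 fell (median 0.38). PHLDA3 rose from 5.20 ± 0.305 to 51.8 ± 2.79 CPM (SD, n = 3; 3.32) and FDXR by 1.74, with CDKN1A as above, while the proapoptotic PMAIP1 changed by −1.39. Of those named after their values were seen, the death receptor gene FAS rose from 0.254 ± 0.191 to 2.195 ± 0.824 CPM (3.09), EDA2R by 2.28, GADD45A by 1.40 and BAX by 0.61. MDM2, the negative regulator of p53, stood at −0.19, and at 0.07 with total counts only and 0.12 with TPM. Of 29 genes of amino acid and unfolded protein stress 17 fell, 9 rose and 3 were not called (median −0.57; camera adjusted p = 2.30e-10, and adjusted p = 0.134 with an estimated correlation). Those that fell most clearly were SLC7A11 and the serine and one-carbon enzymes PSAT1 (−2.98), SHMT2 (−2.00) and MTHFD2 (−1.93). The median of the list was −0.24 with GC content and length fitted out and −0.30 with total counts only, where 16 fell and 12 rose. Of 24 cholesterol synthesis genes 17 rose, 2 fell and 5 were not called (median 0.44; camera adjusted p = 7.75e-06, and adjusted p = 0.0908 with an estimated correlation). With total counts only, 22 rose and 1 fell (median 0.70), and with GC content and length fitted out 18 rose and 5 fell (median 0.61). The sterol desaturase gene SC5D rose by 1.32, HMGCS1 by 0.86 and IDI1 by 0.70.

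**Figure D2:**
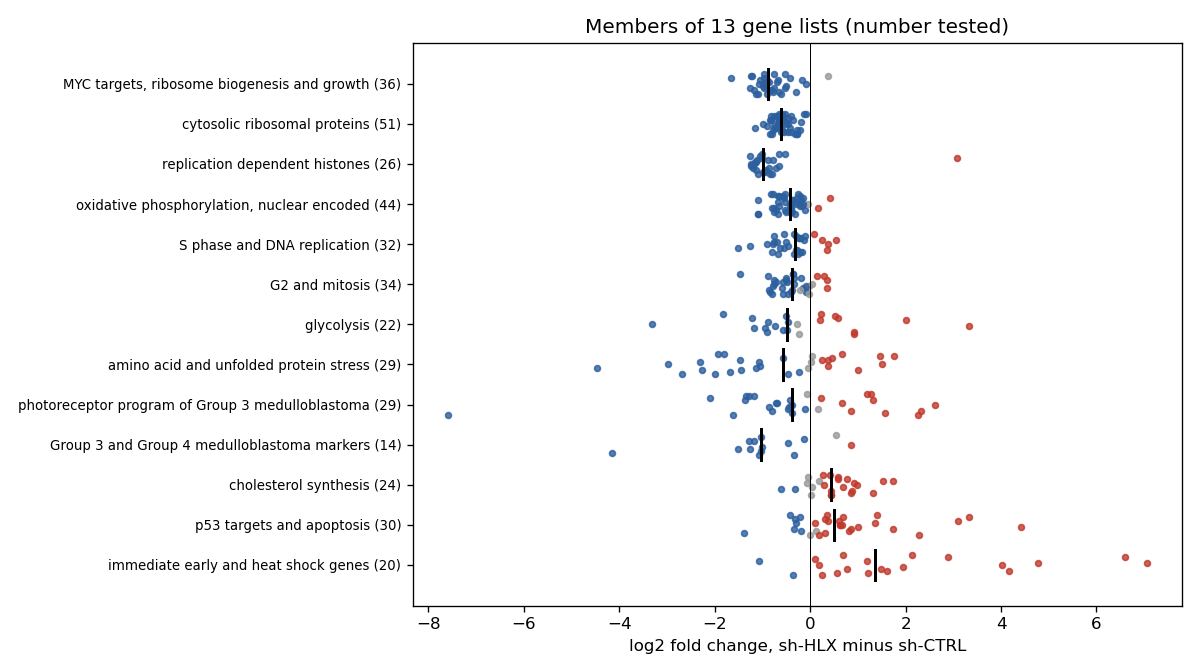
Log2 fold change, sh-HLX minus sh-CTRL (horizontal axis), of each tested member of 13 gene lists, with the number tested after each name; red points rose, blue points fell and grey points were not called (edgeR adjusted p), and black bars are list medians, which run from −1.03 for Group 3 and Group 4 markers to 1.35 for immediate early and heat shock genes. Of the 14 Group 3 and Group 4 markers only 7 had a mean of at least 5 CPM, and their median rests on low counts. The point farthest left, RCVRN, had 0 counts in sh-HLX, so that its fitted position depends on the prior count.

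Markers of medulloblastoma subgroups changed as well. Of 14 tested markers of Group 3 and Group 4 tumours 12 fell, 1 rose and 1 was not called (median −1.03; camera adjusted p = 0.0172, and adjusted p = 0.214 with an estimated correlation). The GABA receptor subunit GABRA5 (−1.27), EYS (−1.29), EYA2 (−1.07) and IMPG2 (−0.47) fell. Only 7 of the 14 had a mean of at least 5 CPM, of which 6 fell and 1 rose. The median lay between LMX1A (−1.02, 1.69 CPM in sh-CTRL) and MAB21L2 (−1.04, 0.688 CPM), both named after their values were seen, so that it rested on low counts. OTX2 (−0.13), among those that fell, turned to 0.14 with total counts only. With total counts only, 8 of the 14 fell and 3 rose (median −0.77), and with limma on log2(TPM + 1) 4 of 9 fell and 2 rose (median −0.37). Photoreceptor genes, which Group 3 tumours express, went both ways, 17 of 29 down, 10 up and 2 not called (median −0.39), and camera did not call the list (adjusted p = 0.0760), except without sh-CTRL replicate 1 (adjusted p = 0.0207). With total counts only, 14 fell and 12 rose (median −0.13), and with limma on log2(TPM + 1) 12 fell and 10 rose (median −0.0963). GNGT1 fell from 968.5 ± 41.1 to 226 ± 8.88 CPM (SD, n = 3; −2.10), GUCA1B changed by −1.62 and PDC by −1.34 (−0.67 with GC content and length fitted out), while the transporter ABCA4 rose from 50.6 ± 0.261 to 243.5 ± 1.91 CPM (2.27). The photoreceptor regulators, named after their values were seen, moved apart, CRX by −0.80 and NRL by 0.85, and RCVRN went from 33, 27 and 24 counts to 0 in each sh-HLX library, at least 19.9-fold lower by a floor of 3 counts over the group. Fewer features had a count in the sh-HLX libraries, as given above, so this loss need not be particular to RCVRN. Of 14 tested markers of SHH and WNT tumours 6 rose, 1 fell and 7 were not called (median 0.34; camera adjusted p = 0.103), with GAD1 (2.67), GLI2 (1.05) and PDLIM3 (0.55) higher. With GC content and length fitted out 6 rose and 4 fell (median 0.0988), and with total counts only 9 rose and 1 fell (median 0.61).

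Interferon response genes were mostly below the detection filter. Of 12 tested, 4 rose, 6 fell and 2 were not called; STAT2 (1.46), IFIH1 (1.97), IRF1 (2.85) and IFI35 (1.83) rose, and MX1, OAS1 and OAS3, named after their values were seen, fell from about 1 CPM. MX1 and OAS3 had 0 counts in sh-HLX and were at least 14.6-fold and 12.6-fold lower by the same floor. As for RCVRN, these falls from a low level need not be particular to these genes. The list's median was −0.24, also with these members at their bound, and its mean −1.34, while camera leaned up (adjusted p = 0.159), and the median turned to 0.02 with total counts only. With limma on log2(TPM + 1), which tested 7 of these genes, 6 rose and 0 fell (median 1.74). Neuronal differentiation genes also went both ways, 9 of 24 up, 10 down and 5 not called (median −0.25, 0.01 with total counts only; camera adjusted p = 0.466): the proneural factor NEUROD1 fell from 396 ± 16.6 to 74.1 ± 3.69 CPM (SD, n = 3; −2.42) and the synaptic vesicle gene SYT1 changed by −2.02, while NEUROG1 rose by 3.03. Of 16 stem and progenitor genes 7 rose and 9 fell; ID1 (2.04) and HES1 (1.94) rose, and NES (−1.10) and EZH2 (−0.50) fell. The median of that list was −0.14, its mean 0.36 and camera up (adjusted p = 0.601), and the median turned to 0.13 with total counts only. Of 18 mesenchymal and matrix genes 7 rose, 8 fell and 3 were not called, with a median of −0.03, a mean of 0.05 and camera up (adjusted p = 0.661), and a median of 0.23 with total counts only; TGFBI (3.33) and FN1 (1.38) rose, and ZEB2 (−2.73) and SPARC (−1.81) fell. Of 10 abundant long noncoding RNAs 5 rose, 4 fell and 1 was not called (median 0.00; camera adjusted p = 0.789). KCNQ1OT1 (1.15) and MALAT1 (0.81) rose, and MIR17HG (−1.73), host of the MYC-activated miR-17-92 cluster, and GAS5 (−0.70) fell.

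Markers of other brain cell types, listed for the tumours, were also measured in the cultures. Camera, which compares a list with the other genes, called none of these 7 lists, at adjusted p from 0.382 to 0.933. Fry, which does not compare them with other genes, called all but the microglia and macrophage markers (adjusted p = 0.0622), at adjusted p from 2.88e-05 to 0.0101. Of 9 oligodendrocyte markers 6 rose and 2 fell, with CNP (0.51) and MYRF (1.11) higher, APOD higher by 2.18 and UGT8 lower (−0.83). Of 10 astrocyte markers 4 rose and 4 fell, with APOE (2.02), ALDOC (2.01) and CLU (1.08) higher and SLC1A3 lower (−0.75). Of 6 microglia and macrophage markers 3 rose and 0 fell; CSF1R rose by 0.55 and MRC1 by 0.51. The call of CSF1R ended without sh-CTRL replicate 2 (edgeR adjusted p = 0.150) or 3 (0.0736) or without sh-HLX replicate 1 (0.102) or 2 (0.0754), and that of MRC1 without sh-CTRL replicate 2 (0.113) or 3 (0.148) or without sh-HLX replicate 1 (0.115), 2 (0.0721) or 3 (0.0730). With DESeq2 neither was called (adjusted p = 0.273 and 0.309), and MRC1 was not called with median-of-ratios factors (0.0517) or with no filter (0.0576). Of 9 endothelial markers 2 rose and 6 fell (median −0.73, camera up); FLT1 (1.36) and ROBO4 (2.36) rose, and ERG (−1.96) and PODXL (−0.31, −0.04 with total counts only and not called there) fell. Of 10 mural and fibroblast markers 3 rose and 5 fell, with PDGFRB (2.26) and RGS5 (0.54) higher and COL6A3 (−2.99) and MYH11 (−0.72) lower. Of 9 cerebellar neuron markers 3 rose and 2 fell (median −0.07, camera up, 0.20 with total counts only), with FAT2 (1.11), RELN (0.74) and ITPR1 (0.48) higher and GRM4 (−3.24) lower. Of 5 erythroid and choroid plexus markers 2 rose and 2 fell (median −0.13, mean 0.07, camera up, median 0.14 with total counts only). AQP1 (2.29) and KCNJ13 (0.67) rose and SLC4A1 fell (−2.17); the call of KCNJ13 ended without sh-CTRL replicate 2 (edgeR adjusted p = 0.0524) or sh-HLX replicate 2 (0.0962), and with DESeq2 (0.172). The median was also that of OTX2, a Group 3 transcription factor gene at 2389 ± 42.0 CPM in sh-CTRL, which stood at −0.13 and turned to 0.14 with total counts only.

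Camera with the preset correlation called 15 of 29 lists, and 0 of these 15 calls held with an estimated correlation. A higher correlation alone does not account for every loss. The estimate was 0.753 for cytosolic ribosomal proteins, but −0.00758 for cholesterol synthesis and 0.00985 for Group 3 and Group 4 markers, no higher than the preset 0.01. Adjusted over the list alone, the member counts were as over all genes tested, except for glycolysis (8 rose, 14 fell), interferon response (4 rose, 7 fell), microglia and macrophage markers (1 rose, 0 fell) and abundant long noncoding RNAs (5 rose, 5 fell). Among protein-coding genes with a mean of at least 5 CPM, those with a GC content of 30.2% to 41.4% had a median log2 fold change of −0.31 and those with 55.5% to 73.8% a median of 0.22.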

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

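Of the tests in this part, those of sequencing depth, of GC content and length on the number of calls and on the immediate early genes, and of a gained or lost chromosome segment had their expected outcome written before the result was seen; the splits of the samples, the replicate spread, the random gene orders with and without correction, and the variation of the immediate early genes were tests chosen after it. Groups of 3 were too small to test single samples as outlying.

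The summed CPM of the oligodendrocyte markers was 180.1 ± 16.1 (SD, n = 3) in the ASO-CTRL tumours, whose libraries enter no comparison, above the 128 ± 2.80 of the sh-CTRL and 153 ± 2.202 of the sh-HLX cultures. The summed CPM of the cerebellar neuron markers was 159 ± 11.1 in the same tumours, above 90.8 ± 1.58 and 123 ± 3.52. ITPR1 (84.3 CPM in the tumours, 42.8 in sh-CTRL), RELN (28.0 and 11.5) and FAT2 (18.3 and 10.7), named after their values were seen, carried most of it and are expressed by the cultured line, so that the sum does not show cerebellar neurons. The summed CPM of the astrocyte markers was 994.6 ± 21.4 in the tumours, against 985.5 ± 5.14 and 997.3 ± 22.7 in the sh-CTRL and sh-HLX cultures. It was carried by GLUL (560.8 CPM in the tumours, 698.3 in sh-CTRL) and SLC1A2 (310.7 and 222.8), also named after their values were seen and expressed by the line, so that the sum excludes no astrocytes.

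The first pattern is the extent of the change, with 14576 of 20513 genes called. Depth differed between the groups, but with all libraries thinned to 10793172 counts 84.2% of the calls remained in the same direction, and with GC content and length fitted out 84.7% of the called protein-coding genes remained, with 421 reversed, which argues against either as the whole source. The 6 libraries can be split 3 against 3 in 10 ways, of which 1, the real one, gave as many calls; edgeR and DESeq2 each called 0 genes in the highest of the others (edgeR 58 to 120 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Open as well is whether the replicates are repeats of a single culture per group: a biological coefficient of variation of 2.09% is low, but every pair differed by more than counting noise. Targeting HLX, the difference that the design names, could not be told apart from other differences between such cultures.

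The second pattern is regional: on chromosome 12, 30 neighbouring protein-coding genes from SOX5 to YARS2 (23529500 to 32755902; SOX5 −2.37, INTS13 −1.71 and DNM1L −1.06 were named after their values were seen) had a median log2 fold change of −0.96, with 25 of the 30 lower, and 30 from TBC1D15 to CRADD −0.94, as had 30 on chromosome 6 that include histone genes. In a permutation test of gene order no random order gave a window as far from 0 as the first (p = 0.001, the smallest that 1000 orders can give), which argues against chance order. With GC content and length fitted out the largest window was another on chromosome 12, from SYT1 to LTA4H (−0.66, permutation p = 0.003). That argues against the GC and length trend as the whole source on the chromosome, although windows past the limit fell from 150 to 26 of 9423. The segment from SOX5 to YARS2 came to −0.58, only just past the limit of 0.57. A window that overlaps it, from PPFIBP1 to PUS7L, was at −0.63 and also past the limit. These values argue against the trend as the whole source there, though for the segment itself the margin was small. A copy-number difference between the cultures stays open: after correction 76.7% of the 30 genes from SOX5 to YARS2 (23) lay below the median of all genes, but their interquartile range of 0.90 was wider than the 0.77 of all genes. The ASO-CTRL tumours lay −0.01 from sh-CTRL and 0.68 from sh-HLX at its median before correction, and shared regulation of these genes was not tested.

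The third pattern is the immediate early genes, of which 13 of 13 rose, by 0.18 to 7.06 (median 2.14). With GC content and length fitted out 96.1% of the median remained, which argues against that trend as its source. Handling at harvest could raise these genes, and if it varied between single cultures it would spread the sh-HLX libraries: their coefficient of variation was, at the median, 1.802 times that of genes of like level, between the bounds set for a clear answer. Handling that differed between the groups as a whole cannot be told apart from an effect of the hairpin, since it would follow the groups.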

How the results depend on the processing

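Alternatives added after the data were seen are total counts without TMM factors, glmTreat, thinning, the GC and length correction and the fit of 9 libraries. The count of 14576 called genes stayed within 1.5 times under all alternatives except glmTreat. It was 14566 with DESeq2's median-of-ratios factors, 20087 of 67194 with no filter and 14723 with at least 10 counts per library. DESeq2 called 13398 of 42895 (5538 higher, 7860 lower), and limma 13821 on log2(TPM + 1) and 13619 on log2(TPM + 0.1). The count was 14512 without mitochondrial, ribosomal protein and haemoglobin genes, 14347 in the fit of 9 libraries and 15125 with total counts only. After thinning it was 12520, where 12274 of the calls remained. Similar counts did not mean the same genes. DESeq2 kept 11312 of the 14576 calls in the same direction, and limma on log2(TPM + 1) kept 9963 of the 12874 among genes it tested. Leaving out single replicates gave 13919 to 15305 called genes. Against a 2-fold change glmTreat called 2947 genes (1397 higher, 1550 lower), by construction a stricter question. Genes called and changed at least 2-fold were 4917, but 11482 with no filter, where more genes with low counts are tested. Calls in the opposite direction were 577 and 573 with limma on TPM and 451 with total counts only, and 421 among protein-coding genes with the GC and length correction.

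The replicate numbers did not pair the samples: over 11076 genes the deviations of same-numbered libraries correlated at 0.025, 0.056 and −0.056. With the replicate block 14535 genes were called, 14472 of them as before, and the call of MRC1 was lost (edgeR adjusted p = 0.0574). In this hint from the data, not the design, replicate 3 of sh-HLX correlated better with another number.

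Among named genes, OTX2 (−0.13) reversed to 0.18 with either TPM alternative, 0.14 with total counts only and 0.0889 with GC content and length fitted out, and MDM2 (−0.19) to 0.12 with either TPM alternative and 0.0748 with total counts only. The median shift of 0.26 for total counts exceeds these changes; the cause was not tested further. Calls of named genes lost were 60 of 162 with glmTreat, at most 6 under any other alternative, and 3 of 150 with the GC and length correction (TBX2, MT-ATP8, CSF1R). CSF1R lost its call without sh-CTRL replicates 2 or 3 (edgeR adjusted p = 0.150, 0.0736) or sh-HLX replicates 1 or 2 (0.102, 0.0754), MRC1 without any but sh-CTRL replicate 1 (0.0721 to 0.148), KCNJ13 without sh-CTRL replicate 2 or sh-HLX replicate 2 (0.0524, 0.0962) and CASC8 without sh-CTRL replicate 3 or sh-HLX replicate 1 (0.0782, 0.160). Of list calls, hypoxia was lost with no filter (adjusted p = 0.282), and mitochondrial, tricarboxylic acid cycle and hypoxia genes with total counts only (0.0725, 0.0565, 0.0725); the cause was not tested.

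No analysis of the tumour comparisons was run, nor the fit of all 18 libraries, the covariate of host markers or the shared calls, because 9 columns carry no schedule. Depth limits genes near 1 CPM, which had about 10 counts in the shallowest culture.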

Other observations

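Of the genes around MYC on chromosome 8, some fell with it and CASC8 did not. CASC11, a noncoding RNA just upstream of MYC, fell from 3728 ± 116 to 2061 ± 84.3 CPM (SD, n = 3; log2 fold change −0.85, edgeR adjusted p = 8.31e-45). PVT1, downstream, changed by −0.47, POU5F1B by −0.42 and PCAT1 by −0.33, while CASC8 was called higher, at 0.19 (edgeR adjusted p = 0.0172). These genes were named after their values were seen, and the neighbourhood as a whole was not tested. PVT1, POU5F1B and PCAT1 were not called with limma on TPM, POU5F1B and PCAT1 not with total counts only, and CASC8 not without sh-CTRL replicate 3 (edgeR adjusted p = 0.0782) or without sh-HLX replicate 1 (0.160), and not with DESeq2 (0.249). MYC and CASC11 fell under each of these scalings.

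The 3 ASO-CTRL tumours were scaled together with the 6 cultures. The only genome build named is human, and no step that removes mouse reads is named. Tumour values may therefore mix reads of the line with reads of the mouse brain. HLX was at 11.2 ± 1.98 CPM (SD, n = 3) and MYC at 1146 ± 7.48, near the sh-CTRL cultures at 10.8 ± 0.797 and 1097 ± 48.6. Genes that rose in sh-HLX did not all lie one way in the tumours. Below their sh-HLX levels were EGR1 at 1.23 ± 0.312, FOS at 2.82 ± 1.02, JUN at 16.5 ± 0.337 and CDKN1A at 1.90 ± 0.402 CPM. Above theirs were, among others, ITPR1 at 84.3 CPM against 61.9 in sh-HLX and RELN at 28.0 against 20.1. BCAT1 was at 543 ± 7.46 CPM, below sh-CTRL at 860.2 ± 9.86 and above sh-HLX at 35.1 ± 1.78. TBX2 was at 7.04 ± 0.437, above every culture. The myelin gene MBP was present in the tumours, at 34.7 ± 9.91 CPM against 1.51 ± 0.155 in sh-CTRL. So were astrocyte genes, with ALDOC at 16.5 ± 3.23 CPM against 0.937 and SLC4A4 at 6.95 ± 1.63 against 0.479. Of 19 astrocyte markers 12 lay above all cultures in all 3 tumours, as did 5 of 16 oligodendrocyte, 7 of 19 cerebellar neuron, 5 of 22 microglia and macrophage, 3 of 20 endothelial, 3 of 17 mural and fibroblast, and 2 of 15 erythroid and choroid plexus markers. The same share over all genes is not given here, so these counts alone show neither presence nor absence of a cell type. No test was run between tumours and cultures, which differ in material as well as in treatment.

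Beyond the segment described above, chromosome 12 as a whole was lower in sh-HLX, with 380 of 528 protein-coding genes with a mean of at least 5 CPM below 0 and a median log2 fold change of −0.34, or −0.26 with GC content and length fitted out. Chromosome 18 had a median of −0.44, or −0.29 corrected, over 149 genes. Chromosome 19, the richest in GC, had the highest median before correction, 0.20, or 0.09 corrected. After correction the medians of chromosomes 8 (0.21) and X (0.18) were higher.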
